A study of Mus musculus with 2 samples.

How the data were processed

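Each of the 2 libraries was made by ATAC-seq from 50000 hematopoietic stem cells of male C57BL/6J mice aged 5 to 6 weeks, per the labels. The labels call them biological replicates and give separate biosamples under the same donor identifier, so whether they came from separate animals is open. All values come from peak lists in the mm10 assembly, made by a uniform processing pipeline, per the labels and the deposited file notes. The aligner, the peak caller, the adjustment of read ends for the transposase offset and the treatment of mitochondrial reads are not given in the sources used here. The label of replicate 1 names a pair of sequencing instruments and that of replicate 2 names none, so an instrument effect could not be separated from the replicates.

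The deposited lists give a signal value per peak, which the authors' peak caller assigned, and the −log10 of a p-value and a q-value per peak. Per the deposited file notes, the per-replicate lists derive from that library alone and the series-level lists from both, except that the sources of an archived series-level list were not used here. The irreproducible discovery rate (IDR) measures how well the ranks of peaks match between subsamples of a library or between libraries. In the series-level files every peak of a thresholded list had a deposited −log10 global IDR of at least 1.30, checked against the ranked lists. The main lists were the IDR-thresholded list of each replicate, and the less strict ones the pseudoreplicated lists. Signal values were used to rank and describe peaks within a list, to correlate the replicates, and to compare parts of the genome within a list. No counts per peak were used, so depth and its precision are unknown, and intervals cover counting of peaks or genes only.

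Many intervals are listed once per summit: 34499 lines gave 25141 intervals in replicate 1, and 34174 gave 24495 in replicate 2. Each interval was counted once, at its strongest summit, on the assembled chromosomes. Peaks were called shared at an overlap of at least 1 bp. Distal peaks and motifs used replicate 1 peaks that overlap a replicate 2 peak, and locations used merged regions. Genes came from the protein-coding set of a GENCODE annotation for the same assembly, whose chromosome lengths match. A promoter was 1000 bp either side of any TSS of a gene, and a gene was called open when each replicate had a peak over any of its promoters; in 37 of the 9030 such genes, none of them in a gene list, the peaks of the replicates did not overlap over the same promoter. Distal peaks had a summit over 1000 bp from every such TSS and were assigned to each gene with a TSS within 50 kb. Motif windows were 101 bp long, and consensus matches on either strand were counted in them and in an equal number of windows outside every list used, matched in GC bins of 5%.

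Gene lists were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 17 lists. Mean distal peaks were compared with 100000 random lists of the same size in a two-sided permutation test, adjusted likewise. Motifs were compared by Fisher's exact test, two-sided, adjusted over 44 tests. Genes and windows are the units in these tests, so their p-values do not measure the spread between animals. Of the listed genes, Ahsp, H19, Kcnq1ot1 and Meg3 had no protein-coding entry and were left out; Hoxa9, Ndn and Cdkn1c stood in more than 1 list.

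The 17 gene lists, the 22 motifs, the tests, the alternatives and the rule for named genes were fixed before the data were examined. That rule named every stem cell transcription factor, up to 3 open genes with the highest mean signal percentile and up to 3 genes without a peak from every other list, the 10 genes with the most distal peaks (ties taken in alphabetical order), and all Hoxa and Hoxb genes; results for some of these genes are not reported here. The alternatives were other overlap rules, promoter and distal windows, the series-level lists, the less strict lists, the 50% strongest peaks, each replicate alone, CpG-matched or otherwise matched backgrounds and flanking motif controls. Alternatives without peaks on repeated or mitochondria-like sequence, and with overlapping peaks required over the same promoter, were added after the data had been seen.

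The tests were run on simulated data first. With 21853 genes and lists of 20, the promoter test called 98.5% of lists planted at 90% open and 2.5% of unchanged lists. The distal test called 76.5% of lists planted at 2 times the mean and 6% of unchanged lists. The motif test called 100% of motifs planted in 5% of 5000 windows and 2% of unplanted ones. Calls in these simulations used an unadjusted p under 0.05. The simulated promoter background was 50% open, against 41.3% in the data. Distal counts were drawn independently per gene, with a higher mean than the 0.717 of the data, and motif windows were random sequence. These rates therefore do not carry over directly to the adjusted tests below. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and blastn 2.17.0.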

Results

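Chromatin accessibility was measured by ATAC-seq in primary hematopoietic stem cells of adult male C57BL/6J mice aged 5 to 6 weeks. ATAC-seq uses the Tn5 transposase to insert sequencing adapters into DNA that is not wrapped in closed chromatin, so stretches with many insertions are called as peaks of open chromatin. Hematopoietic stem cells are the rare bone marrow cells that renew themselves and give rise to all blood lineages. The series held 1 group with 2 biological replicates, each a library from 50000 cells. The comparisons were therefore between the replicates, between classes of genome sequence and between sets of genes, and no comparison with another cell type was made. The replicate 1 list held 25141 peaks with a median width of 473 bp, covering 12.7 Mb of mm10. Replicate 2 gave 24495 peaks with a median width of 494 bp, covering 12.9 Mb. Read depth is unknown from peak lists, so a missing peak was read as not called at this threshold and never as closed chromatin. Genes described below as open or as without a promoter peak are so in the thresholded lists, unless another list is named.

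The first comparison asked how far the open regions of the replicates coincided. Of the replicate 1 peaks, 19727 (78.5%, 95% Wilson interval 78.0 to 79.0) overlapped a replicate 2 peak, and 19640 replicate 2 peaks (80.2%, 79.7 to 80.7) overlapped a replicate 1 peak. Random placement of the peaks on their own chromosomes gave 1.02% and 1.04% on average over 100 placements, with maxima of 1.18% and 1.28%. Most peaks missing from the other list fell below its threshold: 92.9% of the 5414 unshared replicate 1 peaks and 92.1% of the 4855 unshared replicate 2 peaks lay on a peak of the other replicate's less strict list. Shared peaks were stronger and wider. Their median signal value was 9.24 against 6.91 for unshared peaks in replicate 1, and 10.2 against 8.20 in replicate 2, with median widths of 507 against 342 bp and 527 against 363 bp. Across 19514 peak pairs the log2 signal values correlated with a Pearson r of 0.83 and a Spearman rho of 0.814. Peaks are not independent replicates, so no p-value was attached to this correlation.

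Open chromatin was concentrated at gene starts. Merging overlapping peaks of both replicates gave 19510 shared regions with a median width of 578 bp, and 43.1% of them (95% Wilson interval 42.4 to 43.8) had their summit within 1000 bp of a protein-coding transcription start site (TSS). Such sequence made up 2.44% of the assembled genome, an enrichment of 17.7-fold. Introns held 25.3% of the regions against 35.1% of the genome, intergenic sequence 29.5% against 60.1%, and exons outside promoters 2.10% against 2.33%. Peaks found in a single replicate lay at promoters less often, in 25.5% (24.4 to 26.7) of 5414 cases for replicate 1 and 16.2% (15.2 to 17.3) of 4855 for replicate 2. The promoter share depended on list depth, falling to 27.5% of the regions shared by the less strict lists.

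Autosomes differed modestly in peak density and the X chromosome stood below all of them. The median autosome held 7.86 shared peaks per Mb, from 6.19 on chromosome 14 to 10.4 on chromosome 11. The X chromosome, present in a single copy in these male cells, held 481 shared peaks, or 37.4% of the autosomal median density (34.3 to 40.9, Wilson interval of its peak count). It also had fewer protein-coding genes, 5.80 per Mb against an autosomal median of 8.03. Per protein-coding gene the X held 0.507 shared peaks against 0.672 on chromosome 7, the lowest autosome, and a median of 0.985. The Y chromosome lay lower still, with 8 shared peaks, or 0.0908 per Mb and 0.0437 per protein-coding gene.

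**Figure D1:**
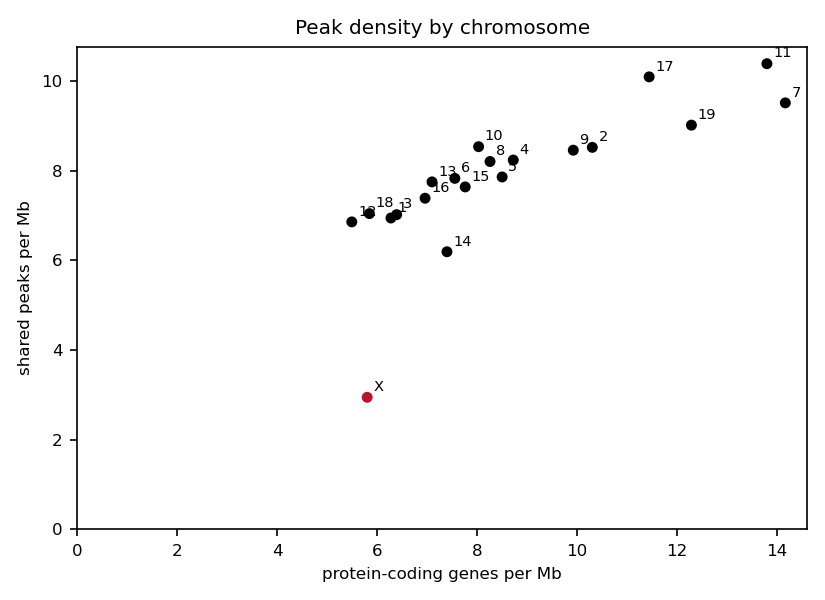
Shared peaks per Mb (vertical axis) against protein-coding genes per Mb (horizontal axis), 1 point per chromosome, autosomes in black and X in red, with Y left out. Autosomes rise together from chromosome 14 at 6.19 to chromosome 11 at 10.4 peaks per Mb, and X lies below them all.

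Promoters of housekeeping, proliferation and interferon genes were open in both replicates more often than those of other genes. Of 21853 protein-coding genes, 9030 (41.3%) had a peak within 1000 bp of a TSS in both replicates, and 1632 had one in a single replicate. Ribosomal protein genes led the 17 gene lists with 21 of 24 promoters open (87.5%, Wilson interval 69.0 to 95.7; adjusted p = 1.1e-04, Fisher's exact test). Rpl27, Rpl11 and Rplp0 had the strongest promoter peaks of that list, and Rpl27 reached signal values of 15.1 and 14.7. Cell cycle genes had 18 of 24 promoters open (75.0%, exact test, adjusted p = 0.0054), led by Ccna2 and Ccnb2, cyclins of S phase and mitosis, and Top2a, the topoisomerase of dividing cells. Ccna2 reached signal values of 16.8 and 18.5. No promoter peak was called in either thresholded list for Ccnd1 and Ccnd2, D-type cyclins, or for their partner kinase Cdk6. Each of these genes had one in the less strict lists of both replicates, where 23 of 24 cell cycle promoters were open. Interferon response genes had 15 of 20 promoters open (75.0%, exact test, adjusted p = 0.0077). Among the strongest were Stat2 and Irf9, transcription factors activated by type I interferon; Stat2 reached 17.8 in replicate 1 and 18.2 in replicate 2, above 99% of peaks in either list. Isg15, Oas2 and Ddx58 had no promoter peak in either thresholded list, and Ddx58 had one in the less strict lists of both replicates.

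Promoter CpG content went with these differences. By tertile of the observed to expected CpG ratio, 7.92%, 51.2% and 64.8% of promoters were open. Against genes of the same CpG tertile the ribosomal list (exact test, adjusted p = 0.030) and the interferon list (2.8e-04) stayed above their background, whereas the cell cycle list did not (0.32). With the 50% strongest peaks of each list alone, the cell cycle (exact test, adjusted p = 0.65) and interferon (0.26) calls were also lost.

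Most blood stem cell transcription factors had an open promoter, but as a list they did not pass the test. Both replicates carried a promoter peak at 10 of 18 genes (55.6%, Wilson interval 33.7 to 75.4; adjusted p = 0.27, Fisher's exact test). Among these were Runx1, Lyl1, Lmo2, Meis1, Hlf, Gfi1b, Mycn, Zfx and Spi1, the gene for PU.1, with signal values of 7.81 and 8.91 at Spi1. Some of these promoter peaks were near the bottom of the thresholded lists: Runx1 had 4.97 and 5.27, the 2.31 and 1.37 percentiles, and Lyl1 had 4.68 and 5.57. The Zfx peak lay on sequence whose summit 31-mer occurred 2 times in the genome. The Lmo2 peak lay at an internal TSS, 11.6 kb downstream of the most 5′ TSS of that gene. Erg, Tal1 and Ldb1 carried a promoter peak in replicate 1 only. Fli1, Gata2, Hoxa9, Mecom and Etv6 had none in either replicate. The call depended on the threshold: with the less strict lists 16 of the 18 promoters were open in both replicates (exact test, adjusted p = 0.014), and with replicate 1 alone 13 were (exact test, adjusted p = 0.045), whereas among the 50% strongest peaks 1 was (5.56% against 25.6% of other genes, exact test, adjusted p = 0.093). Against genes of the same CpG tertile, 54.7% of which were open, the list did not differ (exact test, adjusted p = 1).

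Genes for stem cell surface proteins and niche interaction resembled other genes, with 8 of 19 promoters open (42.1%, exact test, adjusted p = 1). Ctnnal1, Robo4 and Trpc6 had the strongest promoter peaks, and Robo4, a guidance receptor of these cells and of vessels, had signal values of 7.73 and 12.2. Procr and Slamf1, markers used to isolate these cells, had no promoter peak in either thresholded list. In the less strict lists Procr had one in both replicates, and Slamf1 had one in replicate 2 only. The less strict lists raised the count to 17 of 19 (exact test, adjusted p = 0.0095), and the 50% strongest peaks lowered it to 1, or 5.26% against 25.6% of other genes (exact test, adjusted p = 0.093).

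**Figure D2:**
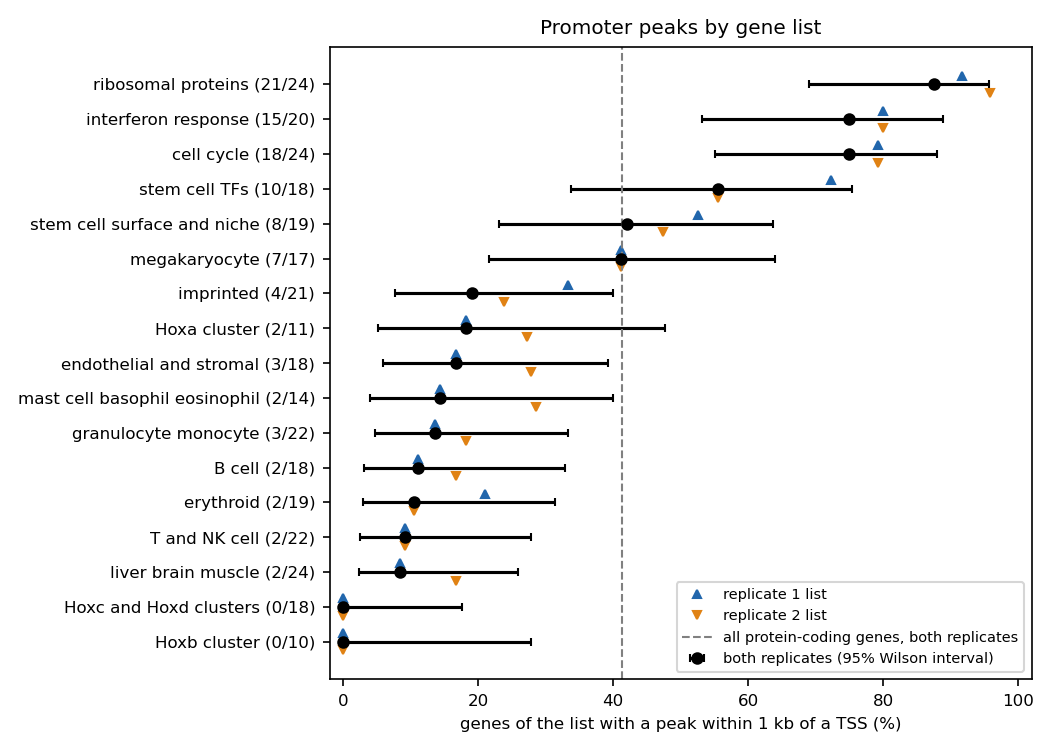
Percent of the genes in each list with a peak within 1 kb of a TSS; black points give genes open in both replicates with 95% Wilson intervals, triangles the list of replicate 1 (up) or replicate 2 (down) alone, and the dashed line all protein-coding genes (41.3%). Ribosomal, interferon and cell cycle genes lie at 75.0% or more, and no Hoxb, Hoxc or Hoxd gene was open.

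Markers of mature blood cells had few open promoters. Erythroid genes were open in 2 of 19 cases (10.5%, exact test, adjusted p = 0.012): Tfrc, the transferrin receptor, and Car2, with Gata1, Alas2 and Slc4a1 among those without a peak. Granulocyte and monocyte genes were open in 3 of 22 (13.6%, exact test, adjusted p = 0.014), namely the myeloid regulators Irf8 and Cebpa and the receptor gene Fcgr3, whose peak summit 31-mer occurred 3 times in the genome. Cebpe, Csf3r and Csf1r had none. B cell genes were open in 2 of 18 (11.1%, exact test, adjusted p = 0.014): Cr2, whose signal values of 19.1 and 23.2 placed it among the 50 strongest shared peaks, and Pax5, with Cd79a and Cd79b without a peak. T and NK cell genes were open in 2 of 22 (9.09%, exact test, adjusted p = 0.0058), Cd3d and Gata3, whereas Cd3e, Cd3g and Cd4 had none. The shared Cd3d peak (44986220 to 44986865) lay at an internal TSS, toward the 3′ end of the gene (44981786 to 44987339, plus strand). Megakaryocyte genes differed from these lists in value, with 7 of 17 open (41.2%, exact test, adjusted p = 1), led by the regulator Nfe2 and by Plek and Rab27b, while Ppbp, Gp1bb and Gp5 had no promoter peak. Mast cell, basophil and eosinophil genes (2 of 14; Mitf and Prg3 open, Mcpt8, Mcpt4 and Cma1 not) and endothelial and stromal genes (3 of 18; Col1a1, Pdgfrb and Cdh5 open, Kdr, Pecam1 and Flt1 not) did not pass the test, both at an adjusted p of 0.071 by the exact test; in replicate 1 alone both did, at adjusted p of 0.043 and 0.027 by the exact test. Genes of liver, brain and muscle, a control for tissue outside blood, were open in 2 of 24 cases (8.33%, exact test, adjusted p = 0.0034). Snap25 and Apob were open, and Alb, Apoa1 and Ttr were not. Of the genes named here without a peak, Csf3r, Gp5, Kdr and Pecam1 had one in the less strict lists of both replicates. The shared promoter peaks of Pax5, Rab27b and Cdh5 lay inside the gene, over 1000 bp from its annotated 5′ end.

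Many lineage genes have CpG-poor promoters, and against genes of the same CpG tertile the erythroid, granulocyte and monocyte, B cell and T and NK cell lists no longer passed the exact test (adjusted p = 0.58, 0.52, 0.76 and 0.070). Against the same background the mast cell list lay 3.27 points above other genes, and megakaryocyte genes lay at 41.2% against 21.5%, both short of the threshold (exact test, adjusted p = 0.72 and 0.070). In the less strict lists 13 of 22 granulocyte and monocyte promoters were open, 59.1% against 58.0% of other genes, and leaving out replicate 1 took the B cell list to an adjusted p of 0.050 in the exact test.

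Hox genes, developmental regulators that lie in 4 clusters, were largely without promoter peaks. In the Hoxa cluster on chromosome 6, 2 of 11 genes were open in both replicates (exact test, adjusted p = 0.17), among them Hoxa10 with signal values of 9.83 and 9.93. Hoxa7 was open in replicate 2 alone, and Hoxa9, Hoxa11 and Hoxa13 were among those open in neither. None of the 10 Hoxb genes on chromosome 11, from Hoxb1 to Hoxb9 and Hoxb13, had a promoter peak (exact test, adjusted p = 0.014). The 18 genes of the Hoxc and Hoxd clusters, Hoxc4, Hoxc5 and Hoxc6 among them, had none either (exact test, adjusted p = 9.2e-04). In the less strict lists 1 of 10 Hoxb genes, Hoxb1, and 1 of 18 Hoxc and Hoxd genes, Hoxc4, were open in both replicates. Imprinted genes, expressed from 1 parental allele, were open in 4 of 21 cases, led by Impact, Grb10 and Gnas, with Igf2, Dlk1 and Ndn without a promoter peak at this threshold (exact test, adjusted p = 0.070). Impact had 2 shared promoter peaks, and the summit 31-mer of the weaker one occurred 2 times in the genome. The strongest replicate 1 promoter peak of Impact was not shared. The shared promoter peaks of Impact, Grb10 and Gnas lay inside the gene, over 1000 bp from its annotated 5′ end. Neighbouring Hox genes share chromatin, so the exact test overstates their number as independent units; the Hoxb call was lost in the series-level lists (exact test, adjusted p = 0.088 and 0.086), and the Hoxa and imprinted lists passed against genes of the same CpG tertile (exact test, adjusted p = 0.015 and 0.0027). In longer lists these deficits varied: 18.2% of Hoxa promoters were open against 52.0% of other genes in the series-level thresholded list, 54.5% against 54.7% in the conservative list and 45.5% against 58.0% in the less strict lists. Imprinted promoters stood at 38.1%, 52.4% and 66.7% in the same lists, the last of them above the 57.9% of other genes. Dlk1 was among those with a peak in the less strict lists of both replicates.

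Away from promoters, open chromatin clustered around the stem cell transcription factors. Of the shared peaks, 11202 (56.8%) lay over 1000 bp from any protein-coding TSS. The 18 transcription factor genes had a mean of 2.33 such distal peaks within 50 kb (SD 2.63 over genes), against 0.718 in random gene lists of the same size, a ratio of 3.25. Its p of 2e-05 was the smallest the permutation test could give, with an adjusted p of 3.4e-04 over the 17 lists. Interferon genes (mean 1.70, ratio 2.37, permutation test, adjusted p = 0.0058), megakaryocyte genes (1.65, ratio 2.30, permutation adjusted p = 0.012) and granulocyte and monocyte genes (1.45, ratio 2.03, permutation adjusted p = 0.016) also exceeded random lists. Hoxa genes had no distal peak within 50 kb (permutation test, adjusted p = 0.012), although their windows overlap one another. The Hoxb genes from Hoxb2 to Hoxb9 each had 1. Cell cycle (ratio 1.80) and ribosomal genes (1.74) missed the threshold, at permutation adjusted p = 0.053 and 0.071, as did stem cell surface (1.62, 0.21), erythroid (1.54, 0.27), B cell (1.47, 0.36), liver, brain and muscle (1.28, 0.55), endothelial and stromal (1.16, 0.71), Hoxb (1.12, 0.84), imprinted (0.796, 0.70) and Hoxc and Hoxd genes (0.697, 0.59). Mast cell and T and NK cell genes missed it too, at permutation adjusted p = 0.40 and 0.66. Some of these ratios crossed 1 under other settings, such as liver, brain and muscle genes (0.829) and imprinted genes (1.19) in the less strict lists and ribosomal genes (0.912) among the 50% strongest peaks. Among the 50% strongest peaks of each list no excess passed the test, and the transcription factors fell to a ratio of 2.23 (permutation adjusted p = 0.17).

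**Figure D3:**
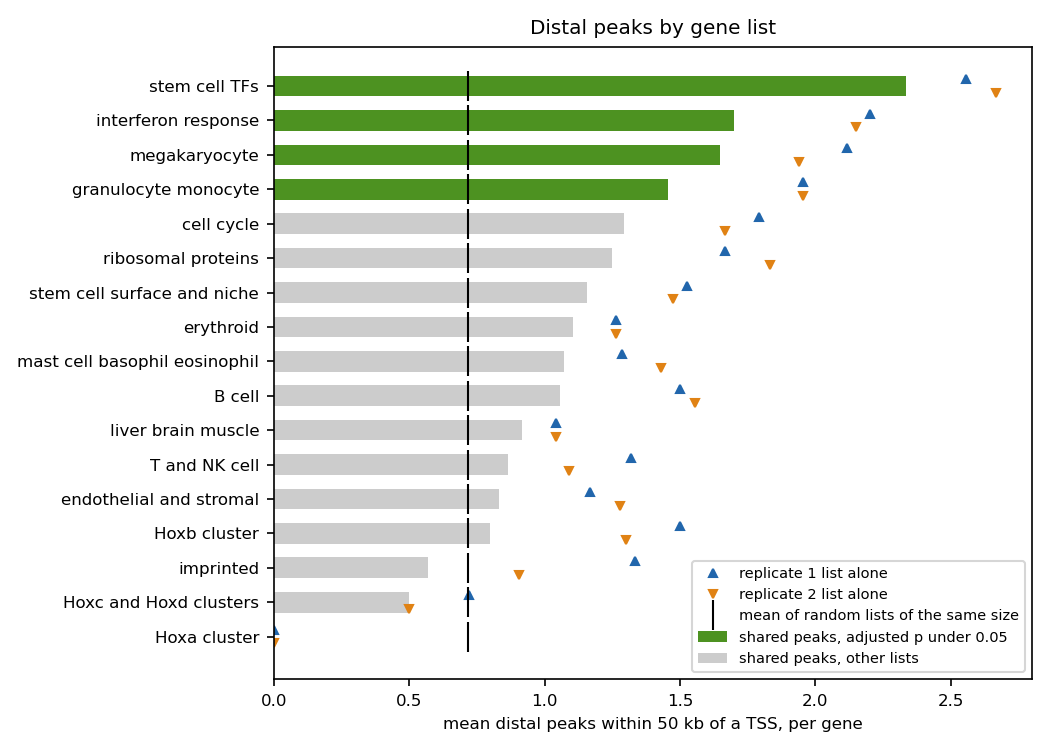
Mean number of distal peaks within 50 kb of a TSS per gene (horizontal axis) by gene list. Bars count peaks shared by both replicates (green, higher than random lists at an adjusted p under 0.05), black ticks give the mean of random lists for shared peaks, and triangles count all peaks of replicate 1 (up) or replicate 2 (down) alone; the stem cell transcription factors have the longest bar at 2.33, and the Hoxa genes have none.

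Several factors without a promoter peak in the thresholded lists had many distal ones. Of these, Mecom had a promoter peak in the less strict lists of both replicates, and Fli1 and Gata2 had none there. Fli1, an ETS-family factor on chromosome 9 (32422204 to 32542861, minus strand), had 9 shared distal peaks, 4 in introns and 5 upstream in intergenic sequence. The strongest of them, at 32556087 to 32556738, lay 13.7 kb upstream of the most 5′ TSS, with a signal value of 9.20 in replicate 1. Mecom, on chromosome 3, had 7, all in annotated introns, the strongest at 30206033 to 30206481 with a signal value of 12.3. Gata2, on chromosome 6, had 4, among them an intronic peak at 88202953 to 88203604, 9.35 kb downstream of its most 5′ TSS. Runx1, on chromosome 16, had 5, the strongest of them intronic at 92801566 to 92802165, 24.3 kb downstream. Tal1, on chromosome 4, had 3, at 19.3, 29.4 and 39.4 kb downstream of its most 5′ TSS and beyond the gene's 3′ end. Lyl1 also had 5, in a gene-dense part of chromosome 8, and Lmo2 had 2. Erg, Meis1, Hlf, Etv6, Ldb1 and Spi1 had 1 each, and Hoxa9, Gfi1b, Mycn and Zfx had none.

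**Figure D4:**
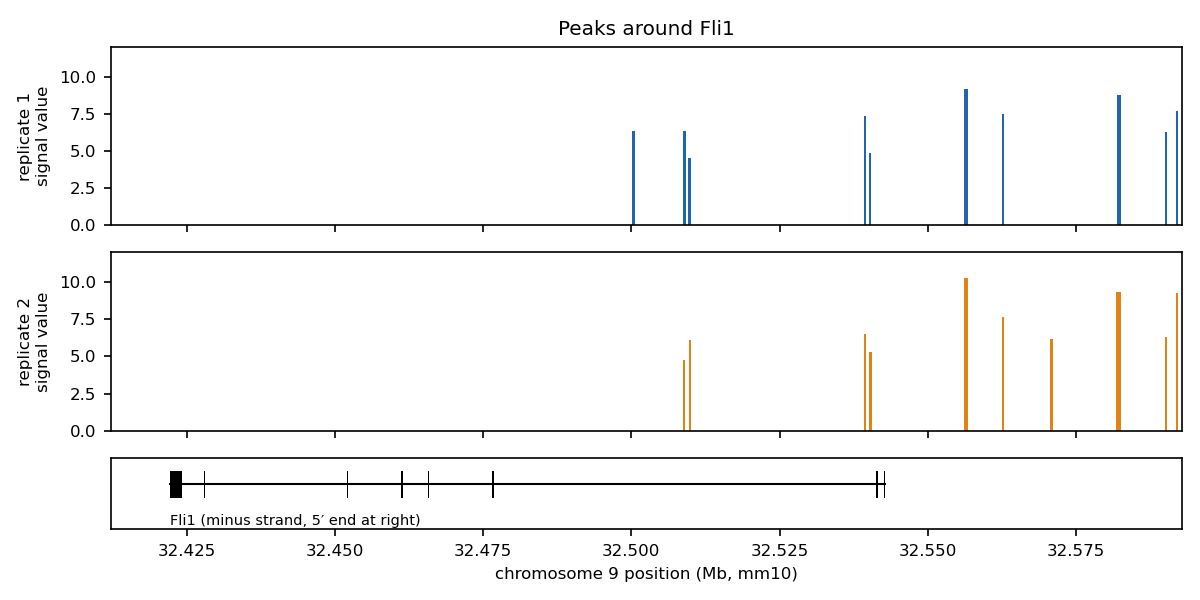
Map of Fli1 on chromosome 9 in mm10, with position in Mb on the horizontal axis and the signal value of each peak on the vertical axis, for replicate 1 (blue) and replicate 2 (orange), above the annotated exons. The 9 shared peaks lie in the 5′ part of the gene and upstream of it, with none within 1000 bp of a TSS.

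Genome-wide, the gene with the most shared distal peaks was Trio, a guanine nucleotide exchange factor, with 11. Fli1 and the phosphodiesterase gene Pde4d had 9 each. Dtnb, E130114P18Rik and Iqsec1 followed with 8, and Adgrg1, Arhgef10, Dnmt3a, Foxp1 and Mecom were among the genes tied at 7. Adgrg1 encodes the adhesion receptor GPR56 of blood stem cells, and Dnmt3a a DNA methyltransferase often mutated in clonal blood cell expansion. Dtnb and Dnmt3a are neighbours on chromosome 12 and shared 4 of these peaks. On average a protein-coding gene had 0.717, and 56.1% of genes had none. This ranking was not adjusted for gene length or number of TSSs. Peaks within 50 kb of any TSS were counted, so a long gene such as Pde4d (1503514 bp) could gather them from more sequence.

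Distal and promoter summits carried many sequence motifs at different rates, and several motifs were enriched in both classes. At the 11202 distal summits, 11.3% of windows held a RUNX motif against 1.79% of GC-matched windows (log2 odds ratio 2.80, 95% interval 2.58 to 3.02). The PU.1 motif was found in 8.39% against 0.607% (log2 odds ratio 3.90, 3.54 to 4.25), and the ETS motif with an ACAGGAA core in 10.1% against 1.52% (2.86, 2.62 to 3.09). The CTCF motif, bound by the insulator protein, was in 5.29% against 0.0803% (6.04, 5.12 to 6.97). AP-1 (5.10% against 1.48%) and IRF motifs (0.795% against 0.0714%) were also enriched at distal summits, with log2 odds ratios of 1.83 and 3.41. GATA motifs were found in 4.97% of distal windows against 3.22% of GC-matched windows (0.65, exact test, adjusted p = 9.8e-11). That direction turned with windows 500 bp to either side as control, which were poorer in GC and held the motif in 6.08% (log2 odds ratio -0.31, exact test, adjusted p = 5.8e-05).

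At the 8525 promoter summits the most frequent motifs were those of general promoter factors. NFY was found in 16.7% of windows against 1.15% of GC-matched windows (log2 odds ratio 4.10, 95% interval 3.80 to 4.39), KLF/SP in 16.4% against 3.86% (2.29), and the ETS motif with a CCGGAA core in 12.9% against 4.02% (1.82). CRE (2.23% against 0.0704%, log2 odds ratio 4.90) and NRF1 (0.739% against 0.0235%, 4.68) were rarer. IRF, CTCF, PU.1 and ACAGGAA motifs were enriched at promoters too, with log2 odds ratios of 3.13, 2.54, 2.19 and 1.34. In turn, CRE (2.36), CCGGAA (1.39), KLF/SP (1.34) and NFY motifs (0.84) were enriched at distal summits. The control windows were matched on GC and not on CpG content. Enrichment of the CRE, NRF1, KLF/SP and CCGGAA motifs, whose consensus contains CpG, was therefore not separated from the CpG content of promoters. The same limit holds in part for the NFY, IRF and CEBP motifs, since some forms of their consensus contain CpG. Of 22 motifs, 12 were enriched and 4 depleted at promoters, and 16 enriched and 1 depleted at distal summits, by Fisher's exact test with adjustment over 44 tests. The depleted ones were TEAD in both classes (log2 odds ratios of -1.10 and -1.20) and MEIS and both E-box motifs at promoters, although neither the CAGCTG E-box (0.12) nor MEIS (-0.0240) was depleted there against flanking windows. With that control, which was poorer in GC, 9 motifs were enriched and 6 depleted at promoters: RUNX, AP-1 and CEBP were no longer enriched, and GATA (-1.54), HOX/PBX (-2.94), MEF2 (-1.66) and HNF4 (-2.29) were depleted. Set directly against promoter summits, distal summits held RUNX (log2 odds ratio 3.14), CTCF (2.97) and PU.1 (2.15) more often, and NFY (-2.69), KLF/SP (-3.11) and NRF1 (-3.30) less often. The largest adjusted p among these 6 differences was 2.4e-15 by the exact test. This comparison was not matched on base composition, with a mean GC content of 63.4% in promoter and 53.5% in distal windows. The GC-matched windows differed too, with KLF/SP in 3.86% for promoters and 0.893% for distal summits.

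**Figure D5:**
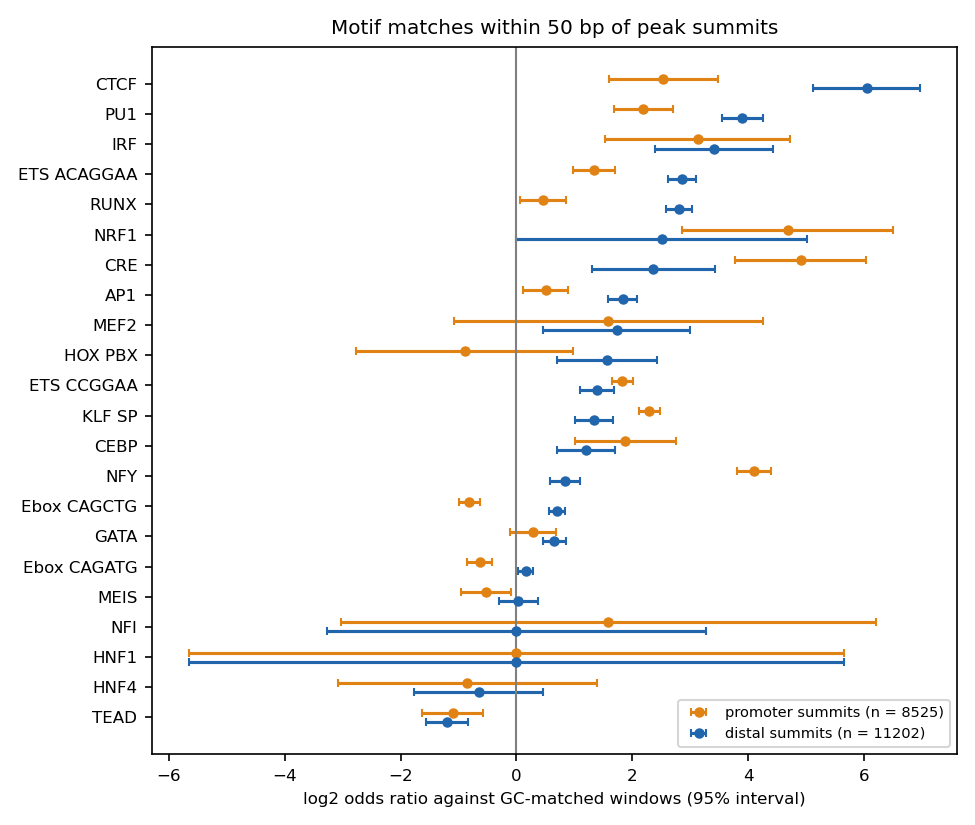
Log2 odds ratio of motif matches within 50 bp of peak summits against GC-matched windows without peaks, for promoter (orange) and distal summits (blue), with 95% intervals. CTCF, PU.1 and RUNX lie farther right at distal summits (6.04, 3.90 and 2.80) than at promoters, and NFY and CRE farther right at promoters (4.10 and 4.90).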

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

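The comparison of the archived list with the current lists and the test of a copy gain were chosen after the result had been seen, the test of the strongest archived peaks was set before its value was known, and the position where the excess begins was estimated from the same list. An archived series-level list that no comparison used held 208607 peaks and, from 47.6 Mb on chromosome 7 through the ends of chromosomes 8 and 9, 3.62 peaks for each peak of the current replicated list against 2.22 elsewhere, an excess of 1.63-fold that drew attention as a signal outside the main measurement. Archived peaks in the upper 20% by signal showed no excess, at 0.956 times the density per gene elsewhere, whereas the rest stood at 1.72 times, which makes more permissive calling of weak peaks in that stretch a candidate explanation. A gain of copies of these chromosomes in the cells stays open: the median current signal inside the stretch over that elsewhere was 1.01 (bootstrap 95% interval 0.992 to 1.02) in replicate 1 and 1.00 (0.988 to 1.01) in replicate 2, but the single-copy X had a higher median than the autosomes, so these medians were not shown to follow copy number. The current replicated list held 0.954 times as many peaks per gene there as elsewhere, which goes against a gain without excluding it, since autosomes differed by more than that. The X chromosome, outside the stretch, held 2.74 archived peaks per current peak. That was above the 1.82 to 2.35 of the autosomes other than chromosomes 7 to 9. What differed in the calling step is open, and no biological explanation other than a copy gain was tested, since the design has a single group.

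The ranked list behind the conservative series-level list held 245 of its 113442 lines on scaffolds outside the assembled chromosomes, which no comparison used.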

How the results depend on the processing

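Effects on results are given here by setting, and the cause was not tested for any of them. The alternatives were fixed before the data were examined, except those for repeated or mitochondria-like sequence and for overlapping peaks over the same promoter, which were chosen after seeing the data, were run for promoters only and changed no promoter call. The share of peaks found in both replicates (replicate 1, replicate 2) was 75.1% and 77.1% at a reciprocal overlap of 50%, 74.8% and 76.8% with summits within 100 bp, 80.6% and 77.8% in the less strict lists, 77.3% and 79.2% among the 50% strongest peaks, and 79.6% and 79.6% at equal list lengths. The Spearman correlation was 0.842 in the less strict lists. The promoter share was 40.4% with 500 bp windows, 46.6% with 2500 bp windows, 32.1% and 29.0% in the series-level thresholded and conservative lists, 27.5% in the less strict lists, 50.5% among the 50% strongest peaks and 37.8% to 39.4% without 1 replicate. X density was 44.4% of the autosomal median among the 50% strongest peaks. The following values are differences in the percent of open promoters, in points, and distal peaks as ratios to random lists. Among the 50% strongest peaks, promoter differences lost the threshold for Hoxb (-25.6), erythroid (-20.3), B cell (-20.0), T and NK cell (-21.1), interferon (14.4), cell cycle (3.60) and liver, brain and muscle genes (-17.3), and passed it for endothelial and stromal (-25.6) and imprinted genes (-25.6). Distal ratios there lost it for stem cell transcription factors (2.23), Hoxa (0), megakaryocyte (2.58), granulocyte and monocyte (1.83) and interferon genes (1.28). Promoter windows of 500 bp took endothelial and stromal genes past it (-28.9), and windows of 2500 bp lost it for B cell (-21.3) and liver, brain and muscle genes (-22.7). The series-level thresholded list lost it for Hoxb (-32.0), erythroid (-25.6) and granulocyte and monocyte promoters (-20.1), and gained it for distal peaks of Hoxc and Hoxd (0.447), cell cycle (1.57) and ribosomal genes (1.93). The conservative list gained it for promoters of stem cell transcription factors (34.2) and distal peaks of ribosomal genes (1.88), and lost it for Hoxb (-34.8) and erythroid promoters (-23.2) and for distal peaks of Hoxa (0.486) and megakaryocyte genes (1.57). The less strict lists gained it for promoters of stem cell transcription factors (30.96), surface genes (31.5) and mast cell genes (-36.6) and for distal peaks of cell cycle (1.54) and ribosomal genes (1.80), lost it for erythroid promoters (-21.1), and reversed the granulocyte and monocyte difference (1.14). Against genes of the same CpG tertile, Hoxa (-42.9) and imprinted promoters (-35.1) passed it, and erythroid (-7.94), granulocyte and monocyte (-7.33), B cell (-4.78), T and NK cell (-17.7) and cell cycle promoters (13.6) no longer did. Without 1 replicate the promoter differences were 11.4 to 26.3 for stem cell transcription factors, -34.9 to -27.5 for B cell, -31.7 to -15.6 for mast cell and -29.3 to -16.4 for endothelial and stromal genes, and the distal ratios 1.71 to 1.79 for cell cycle and 1.66 to 1.88 for ribosomal genes; with replicate 1 alone the stem cell transcription factor, mast cell and endothelial and stromal promoters passed the threshold, with replicate 2 alone the B cell promoters lost it and the distal peaks of ribosomal genes passed it, and those of cell cycle genes passed it either way. Distal windows of 20 kb lost the threshold for Hoxa (0), megakaryocyte (1.74) and granulocyte and monocyte genes (1.65), as did 100 kb for the last (1.53). Random lists matched on gene length took cell cycle (1.83) and ribosomal genes (2.07) past it. Flanking controls, windows of 100 bp either side and the less strict lists each gave 2 depleted motifs at distal summits. Log2 odds ratios of motifs past the threshold reversed with flanking controls for promoter CEBP (-0.0505) and CAGCTG E-box (0.12) and for distal GATA (-0.31), HOX/PBX (-0.20) and MEF2 (-0.0818), and among the 50% strongest peaks for promoter AP-1 (-0.0228). Among motifs short of the threshold, promoter GATA (-1.54) and MEF2 (-1.66) turned to depletion with flanking controls, and distal MEIS (-0.31) with windows of 100 bp either side, all past the threshold. The remaining 336 comparisons of main results kept their call. In some of those without a call the direction turned, among them promoters of stem cell transcription factors (-20.04) and surface genes (-20.3) among the 50% strongest peaks, imprinted promoters (8.72) in the less strict lists and mast cell promoters (3.27) against the same CpG tertile. With peak lists alone, depth cannot be equalised between the replicates. List depth and accessibility are therefore not separable in any change that came with a different peak list.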

Other observations

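The gene families, the count of X peaks per gene and the base composition of unshared peaks were chosen only after the data had been seen. Gene families outside the fixed lists, picked by symbol, divided in the same broad way. Promoters of proteasome subunits were open in both replicates for 34 of 40 genes (85.0%, 95% Wilson interval 70.9 to 92.9), mitochondrial NADH dehydrogenase subunits for 32 of 37 (86.5%), translation initiation factors for 46 of 55 (83.6%) and mitochondrial ribosomal proteins for 62 of 78 (79.5%). RNA helicases of the Ddx and Dhx families (39 of 53) and histone genes (52 of 67) followed. Zinc finger genes named Zfp were open in 266 of 394 cases (67.5%), at a median signal percentile of 80.1 among the open ones. Of 7 Stat genes, the mediators of cytokine signalling, 6 were open. All of these shares were above those of other genes by Fisher's exact test, two-sided, with adjusted p from 2.7e-25 for the Zfp genes to 0.031 for the Stat genes over 19 families.

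Chemosensory receptors and keratins were nearly without promoter peaks. Among 1134 olfactory receptor genes 10 were open (0.882%, 0.480 to 1.62), among 329 vomeronasal receptors 1 and among 53 keratins 0. Of 100 cytochromes P450, 12 were open. Within the immune system, chemokine ligands (2 of 35) and chemokine receptors (2 of 17) also had fewer open promoters than other genes, as did Sox factors (3 of 19), with adjusted p of 4.8e-06, 0.019 and 0.042 by the exact test. Interleukin receptors (14 of 41), integrins (11 of 31), Fox factors (13 of 44) and solute carriers (148 of 371) missed the threshold, at adjusted p of 0.48, 0.60, 0.15 and 0.60 by the exact test. CpG content was not matched in these counts. Neighbouring genes can share a promoter peak, and the exact test on the families counted every gene as a separate unit.

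The strongest shared peaks were unusual in sequence. The tests on them were set before their values were known. Of the 50 shared peaks with the highest mean signal rank, 8 (16%, 95% Wilson interval 8.34 to 28.5) aligned to the mitochondrial genome over at least 50 bp, against 14 of the 19677 other shared peaks (0.0711%), and 14 (28%, 17.5 to 41.7) had a summit 31-mer found more than once in the genome, against 2.21% of the others. The strongest of all, on chromosome 2 at 69355473 to 69355729 with signal values of 42.4 and 42.2, matched mitochondrial DNA at 100% identity over 129 bp. Nuclear copies of mitochondrial DNA that take reads from mitochondria, and repeated sequence, may each account for part of the set. Neither reached the 50% set in advance for a main source of the 50 peaks. Among the 10 highest, 5 aligned to the mitochondrial genome and 5 had a repeated summit 31-mer. In all, 30 of the 50 peaks had neither property. Only exact copies of the summit 31-mer were counted, so near-identical copies could be missed among them. Those 30 included the peak at X 143482940 to 143483175 (33.6 and 33.0) and the Cr2 promoter, and no biological explanation was tested for them.

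The low peak density of X invited a technical and a genomic explanation; the test per gene was chosen after that density had been seen, and the test of promoters before its result. Fewer genes on X cannot account for all of it, since X held 0.507 shared peaks per gene (0.464 to 0.554, Wilson interval of its peak count) against 0.672 on the lowest autosome. A single X copy in male cells could take peaks below the threshold, in which case X should catch up in the less strict lists. The open share of X promoters was 31.3% against 42.1% on autosomes in the thresholded lists, a ratio of 0.744, and 45.4% against 59.0% in the less strict lists, a ratio of 0.768. The rise of 0.0248 (bootstrap 95% interval -0.0221 to 0.0731) lay below the 0.1 set in advance for that explanation, as did its whole interval. It also lay below the 0.05 set in advance against that explanation, but the interval did not exclude a rise of 0.05. The X peaks that passed had a higher median signal than autosomal ones, 9.83 against 8.54 in replicate 1 and 10.6 against 9.63 in replicate 2. A lower signal is what fewer reads would give if all peaks were kept, but a threshold removes the weak ones, so the explanation stays open with 2 male libraries and no female one.

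The peaks found in a single replicate differed in base composition, with a mean summit GC content of 55.7% in replicate 1 and 53.7% in replicate 2, and shared peaks had 57.7% and 57.5%. The conservative series-level list was the longer of the series-level thresholded lists, with 43478 peaks against 36033.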
